A study of Homo sapiens with 8 samples.

How the data were processed

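RNA from 8 cultures or extracts of stably transfected HEK293 cells, 4 labelled NEO and 4 labelled HCaRG, was measured on 8 single-channel oligonucleotide arrays. Groups, lines and repeat tags were taken from the sample titles. Per the labels, RNA was purified on columns, labelled by in vitro transcription, stained and scanned, and the deposited values are GCOS signals, an intensity on a linear scale that the authors scaled on all probe sets to a target of 500 on every array. In the deposited table the mean over the probe sets left after trimming 2% at each end was 500.06 to 500.08 on every array, so no array was rescaled. No detection calls, scan dates or scanner files were used here, and a GCOS version is not given in the sources used here. GCOS combines the probes of a set within an array and a single factor per array sets the scale, so differences in the shape of the signal distribution stay in the values.

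Signals were used as log2(signal + 50), which understates the change of dim genes; fold changes in the text are on that scale. The 62 control probe sets were left out, and probe sets with a mean signal of at least 200 over the 8 arrays were tested. Of 54675 probe sets, 41097 had 1 gene symbol in the platform annotation, 1801 several and 11777 none; symbols were updated through the gene identifier, which matched for 41043 of the 41097. The 20124 tested probe sets comprised 17776 with 1 gene, 897 with several and 1451 with none, and represented 10418 genes. No gene was named from a probe set with several. Each gene is represented by the probe set of highest mean signal that names only that gene. No genome build applies to the arrays' table, so no coordinates are given.

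Tests were run in R 4.3.3 with limma 3.58.1 (lmFit and eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. HCaRG against NEO used all 8 arrays with the line as a random block (duplicateCorrelation), because repeat arrays of a line are not independent. The estimated correlation between arrays of a line was -0.317, and a negative value narrows the standard error of the group difference. The fold change of that fit is a weighted difference and not the difference of the printed group means. HCaRG-9 against NEO-1 used 6 arrays, and the contrasts involving the single arrays of NEO-6 and HCaRG-8 used a coefficient per line with the spread of the repeat arrays. COMMD5 was also tested by an exact permutation of the 8 arrays, whose smallest two-sided p is 0.0286. Gene lists were tested with cameraPR on the moderated t at a correlation of 0.01, with adjustment over the 29 lists that had at least 5 measured genes, and again with correlations estimated from the residuals. An estimate below 0 was set to 0, which is less strict than 0.01. A further 4 lists had fewer measured genes: proximal tubule and mature nephron with 3, fibroblast and smooth muscle markers with 1, and blood and endothelial markers and stratified and glandular epithelial markers with 0 each.

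The rule for named genes, the lists, the tests and most alternatives were fixed before the data were examined. For HCaRG against NEO the rule took COMMD5, the 15 largest changes each way among genes past the threshold with the groups of arrays fully apart, up to 4 members of each list past the threshold, and 7 genes whatever their values. Of those 7, CDKN1A, MKI67, EGFR and VIM were bright enough to test, and NPPA, TGFA and CDH1 were not. For HCaRG-9 against NEO-1 it took up to 10 genes each way past the threshold. For the other contrasts, where none passed, it took the 5 largest absolute moderated t values, said not to have passed.

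First, Rep and Rep2 tags are shared by NEO-1 and HCaRG-9, so it was checked whether they pair the arrays. Deviations from the line means correlated across probe sets at 0.238 for the arrays without a further tag, 0.224 for Rep2 and 0.275 for Rep, and each array correlated best with the array of its own tag. NEO-1 first with HCaRG-9 Rep2 gave 0.149, and NEO-1 Rep2 with HCaRG-9 first 0.193. Deviations cancel out within a line, so these correlations are not separate checks of the pairing. On these correlations alone the tags were taken to pair the arrays, and values with the tag as a replicate block are given where they change a call or a count. The control probe set dap went against this for Rep. It read 5866 in NEO-1 Rep and 2332 in HCaRG-9 Rep, against 5100 and 5218 in the arrays without a further tag and 1918 and 2014 in Rep2. Whether both Rep arrays came from a shared run is therefore open.

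The fits were tested on simulated data with the real means of the 20124 probe sets, 200 of them changed. With arrays of equal noise and the line as a block, 57% of 2-fold and 92% of 4-fold changes were recovered with 3 unchanged probe sets called. With a single noisy array the same fit recovered 65% and 92%, called 59 unchanged probe sets and estimated a correlation of -0.216; without the block it recovered 33% and 79% and called 3. With a noisy array and no probe set changed, the fit with the block called 0 and estimated a correlation of -0.212. With 7 arrays the fit with the block recovered 59% and 87% and called 0. The simulated correlation between arrays of a line was 0.671 there, against 0.0569 in the real fit without NEO-1 Rep. Array noise was drawn from the spread of NEO-1 first and Rep2 alone, so the rates in this paragraph need not hold for the real arrays. The fit with a coefficient per line, tested on the mean difference, recovered 90% and 100% but called 2892 unchanged probe sets. The comparison of 2 lines on 6 arrays called 6064 probe sets that differed only between simulated lines, so it cannot tell a line from a plasmid. On the real arrays that comparison called 3 probe sets and the fit with a coefficient per line 0, so the simulated noise differs from the real noise. In the simulated list test the shifted list was recovered and 0 others were called. Its noise was drawn separately for each probe set, so it does not check false calls of lists whose genes vary together.

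Alternatives changed the offset (none or 150), the filter (none or 500), the normalization (quantile or median centring), the trend, the handling of lines and of multiple probe sets, a 2-fold minimum, the replicate block, and left out each array in turn. After the data were seen, fits without NEO-1 Rep or without both arrays tagged Rep, array weights, and list tests with the block were added. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.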

Results

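The series compared HEK293 cells, a human line derived from embryonic kidney, that had been stably transfected with a plasmid carrying HCaRG with cells that carried the empty plasmid, called NEO after its selection marker. HCaRG, whose present symbol is COMMD5, encodes a COMM domain protein. Each of 8 samples was hybridised to an oligonucleotide array covering 54675 probe sets, and each sample was synchronized and grown with 10% serum for 48 hours before RNA was taken. The NEO group held 3 arrays of a line named NEO-1 and 1 array of NEO-6, and the HCaRG-labelled group held 3 arrays of HCaRG-9 and 1 array of HCaRG-8. The 3 arrays of NEO-1 and of HCaRG-9 are named here by their tags as first, Rep and Rep2. The labels do not say whether tagged arrays came from separate cultures or whether each line grew from a single cell. The p-values of single probe sets therefore measure only the spread between these samples, which may be technical. Those of gene lists compare the t values of listed genes with those of other genes. They do not measure how a list varies between samples or lines. Signals were scaled by the authors to a trimmed mean of 500 on every array, and 20124 probe sets for 10418 genes were bright enough to test. The number of arrays limits the precision of every value below.

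The labels describe the HCaRG transfectants as overexpressing HCaRG, but the gene on the plasmid, COMMD5, was not measured at a higher level in their arrays. The brighter of the 2 probe sets that name only COMMD5 read 1094 ± 479 in NEO and 1007 ± 188 in the HCaRG-labelled arrays (SD, n = 4 each), a log2 fold change of -0.05 ± 0.17 (SE; limma, adjusted p = 0.871; exact two-sided permutation p = 0.914). The dimmer, below the filter, averaged 106 ± 43.2 and 125 ± 26.1 (SD, n = 4 each; exact permutation p = 0.457). A further 2 probe sets, which the annotation assigns to COMMD5 together with other genes, gave log2 fold changes of -0.03 ± 0.16 and -0.21 ± 0.14 (SE; limma adjusted p = 0.929 and 0.361), and 0.26 and 0.01 without NEO-1 Rep (adjusted p = 0.382 and 0.980). NEO-1 Rep read 1805 on the brighter COMMD5 probe set and the other NEO arrays 761 to 930 (929.7 at most); without it the log2 fold change was 0.20 ± 0.17 (SE; limma adjusted p = 0.650). Whether these probe sets lie within the plasmid's insert is not given in the sources used here, and a probe set outside it checks nothing, so the arrays are called HCaRG-labelled throughout and every direction below is between labels.

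The comparison of the HCaRG-labelled with the NEO arrays asked which transcripts differ in cells transfected with HCaRG. LCP1, which encodes the actin-bundling protein L-plastin, rose most among the named genes, from 69.3 ± 28.5 in NEO to 925 ± 128 in the HCaRG-labelled arrays (SD, n = 4 each; log2 fold change 3.13 ± 0.14, SE; limma adjusted p = 3.55e-06). The rise was 3.18 on the log2 scale for HCaRG-9 over NEO-1 and 2.66 for HCaRG-8 over NEO-6. MMP12, a secreted metalloproteinase that degrades elastin, rose from 111 ± 33.4 to 581 ± 214 (SD, n = 4 each; log2 fold change 2.01 ± 0.16, SE), and the short-chain dehydrogenase gene DHRS2 from 443 ± 248 to 1536 ± 154 (1.90 ± 0.19). The vesicle fusion protein gene VAMP8 rose from 615 ± 240.1 to 2145 ± 321 (1.84 ± 0.17). DUSP22, a dual-specificity phosphatase gene, fell from 1922 ± 149 to 999.9 ± 134 (log2 fold change -0.88 ± 0.11, SE), with all 4 HCaRG-labelled arrays below all 4 NEO arrays.

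EPCAM, an epithelial adhesion molecule, went from 263 ± 84.0 to 1022 ± 259 (SD, n = 4 each; log2 fold change 1.81 ± 0.16, SE; limma adjusted p = 0.00127). FN1, the extracellular matrix protein fibronectin, went from 2829.8 ± 774 to 6624 ± 335 (1.32 ± 0.13, adjusted p = 0.00152), and all 4 of its probe sets were higher. CD24, a glycoprotein of the cell surface, went from 722 ± 269 to 1929.7 ± 667 (1.21 ± 0.18, adjusted p = 0.0179) and was higher on 5 of 5 probe sets. BEX1 rose with a log2 fold change of 1.47 ± 0.17, the synaptotagmin gene SYT15 with 1.74 ± 0.17 and ZCCHC12 with 1.33 ± 0.15 (SE). These 6 genes and LCP1, MMP12, DHRS2 and VAMP8 are the 10 of the 15 largest rises that also passed the test without the NEO-1 Rep array. Without the line block only LCP1 of these 10 passed (adjusted p = 0.000952; 0.159 to 0.634 for the other 9), and with the tag as a replicate block on 6 arrays none did. The other 5 were MAL2, TCIM, RIPPLY3, SYTL5 and the histone gene H2AC6, with log2 fold changes of 1.21 to 2.09 and adjusted p-values of 0.0679 to 0.209 without that array, where the log2 fold change of MAL2 was 1.33 instead of 2.09. In the second pair of lines the log2 fold changes of MAL2, TCIM and RIPPLY3 were 0.19, 0.61 and 0.41, against 2.32, 2.17 and 1.85 in the first. TCIM read 3563 in HCaRG-9 Rep and at most 597 in the other HCaRG-labelled arrays.

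**Figure D1:**
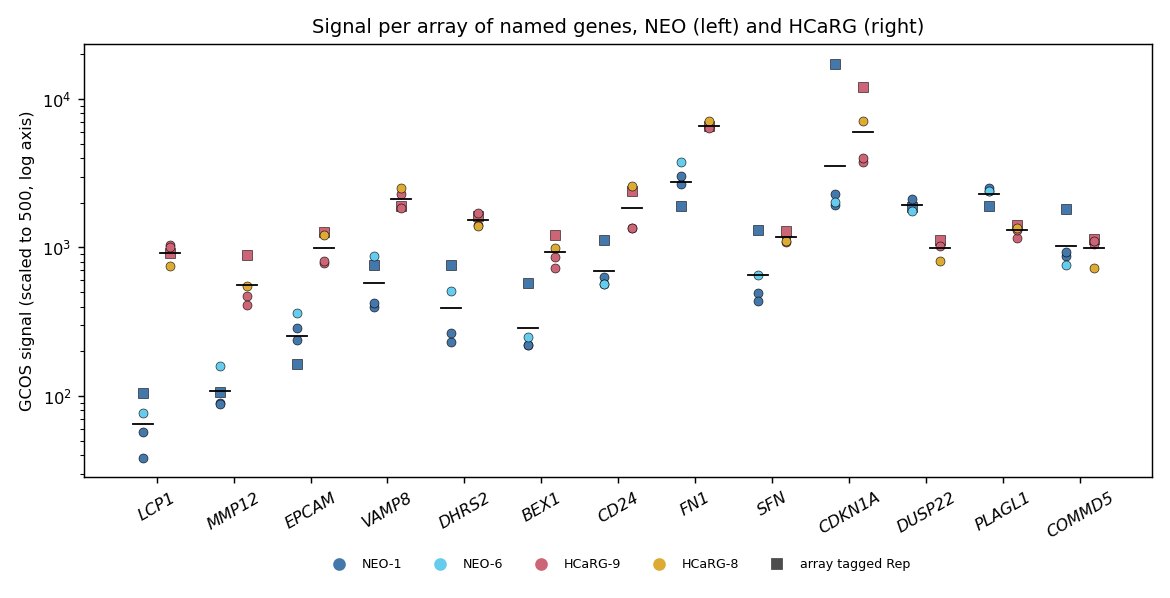
Deposited signal per array on a log axis for 13 genes, with NEO arrays to the left and HCaRG-labelled arrays to the right of each gene; colours mark the lines, squares the arrays tagged Rep, and horizontal lines the geometric mean of the 4 arrays of a group. LCP1 separates the groups most widely, from 38.4 to 105 in NEO and 749.5 to 1035 in the HCaRG-labelled arrays. The groups overlap for COMMD5, CDKN1A and SFN.

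Among the 15 genes that fell most, only DUSP22 also passed without NEO-1 Rep (log2 fold change -0.93 ± 0.15, SE; adjusted p = 0.0219). The histone gene H4C11 fell from 344 ± 136 to 62.4 ± 51.4 (SD, n = 4 each; log2 fold change -1.92 ± 0.21, SE), and EME2, which encodes a subunit of a DNA structure-specific endonuclease, from 1392 ± 422 to 593 ± 206 (-1.18 ± 0.18). ASNS, asparagine synthetase, fell from 7008 ± 1473 to 3980.1 ± 1647 (-0.96 ± 0.18), with HCaRG-9 Rep and HCaRG-8 at 5606 and 5191 and HCaRG-9 first and Rep2 at 2599 and 2524. The remaining members were ZNF853, SHROOM1, DPH5-DT, the lipid transporter gene ABCA3, PRKCQ-AS1, the nuclear receptor gene NR2F1, BUD23, KHDC1, SYCE2, IMMP2L and ZDHHC14, with log2 fold changes from -1.09 to -0.79. NEO-1 Rep was the highest NEO array for each of these 11 genes, and without it their adjusted p-values were 0.110 to 0.291. The log2 fold changes of all 11 moved nearer 0 without it, most for 6 of them: -0.58 for ZNF853, -0.60 for SHROOM1, -0.54 for ABCA3, -0.53 for NR2F1, -0.56 for KHDC1 and -0.46 for ZDHHC14. In HCaRG-8 over NEO-6 the values of ZNF853, SHROOM1, ABCA3, NR2F1, BUD23, SYCE2 and ZDHHC14 were -0.35 to -0.04, against -1.21 to -0.88 in HCaRG-9 over NEO-1. Without the line block none of the genes named in this paragraph passed (adjusted p = 0.384 to 0.987). PLAGL1, an imprinted gene for a zinc finger transcription factor, fell from 2292 ± 270.2 to 1314 ± 110.2 (log2 fold change -0.77 ± 0.11, SE; adjusted p = 0.0115) on all 3 of its probe sets, and passed without NEO-1 Rep too (-0.86 ± 0.12, adjusted p = 0.0154).

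Of 33 gene lists fixed before the data were examined, 29 had at least 5 measured genes, and 4 were shifted toward higher values in the HCaRG-labelled arrays. In the list of TGF-beta and BMP signalling, 4 of 22 measured genes rose, none fell, and 9 rose when adjusted over the list alone (limma cameraPR adjusted p = 0.0025; adjusted p = 0.000457 with an estimated correlation). The 4 were BMP2 (823 ± 129.9 to 1352 ± 227; log2 fold change 0.66 ± 0.12, SE), the receptor gene TGFBR2 (0.64 ± 0.15), ID2 (0.57 ± 0.13) and the inhibitory SMAD7 (0.53 ± 0.11). Without the line block all 4 had a limma adjusted p of 0.987, and with the tag as a replicate block none passed. The log2 fold change was above 0 for 17 of the 22 genes, and for 19 without NEO-1 Rep, where the list's adjusted p was 7.93e-06, no single member passed and TGFBR2 had a log2 fold change of 0.34 (0.22 in HCaRG-8 over NEO-6). Without both arrays tagged Rep the list's adjusted p was 4.18e-06. With an estimated correlation these were 2.42e-06 and 4.88e-07. The estimate for this list with 8 arrays was -0.0152 and was set to 0. The values with an estimated correlation are therefore no stricter check than those at 0.01. In NEO-1 Rep, 14 of these genes were above the mean of the other NEO-1 arrays, with a median log2 difference of 0.37 that lay within the range of -0.72 to 0.54 of signal-matched lists.

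**Figure D2:**
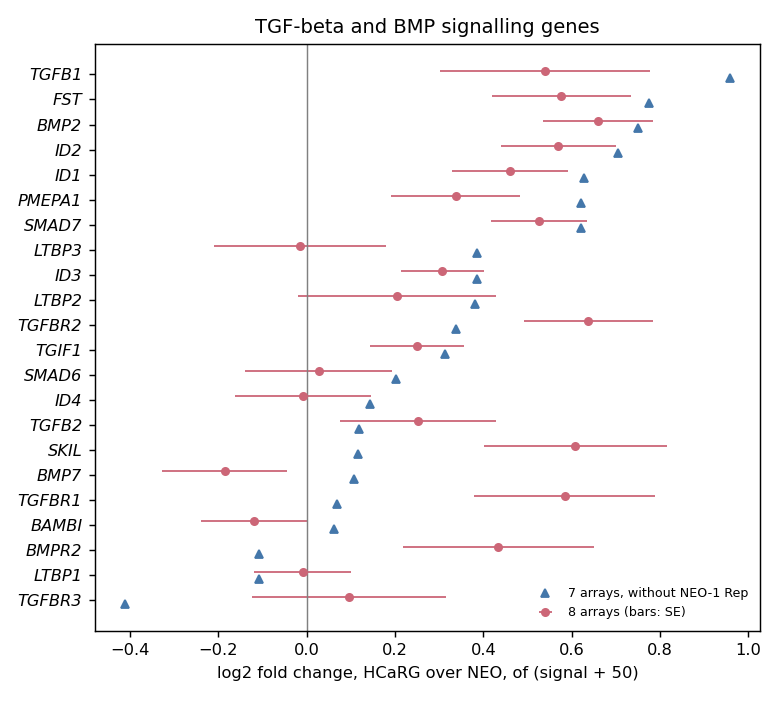
Log2 fold change of signal plus 50, HCaRG-labelled over NEO arrays, for the 22 measured genes of TGF-beta and BMP signalling; circles with SE bars use 8 arrays and triangles the 7 arrays without NEO-1 Rep. The values lie above 0 for 17 genes with 8 arrays and for 19 with 7.

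The list of CDK inhibitors and p53 targets was also shifted higher, with 4 of 25 genes up, none down, and 9 higher and 1 lower when adjusted over the list alone (adjusted p = 0.0156). With an estimated correlation its adjusted p was 0.310. The 4 were TP53INP1 (1096 ± 29.9 to 2048 ± 775; log2 fold change 0.86 ± 0.14, SE), SFN (0.80 ± 0.18), ZMAT3 (0.71 ± 0.14) and the kinase gene PLK2 (0.66 ± 0.15). SFN, which encodes 14-3-3 sigma, passed without NEO-1 Rep as well (1.09 ± 0.16, adjusted p = 0.0166), and the other 3 did not (adjusted p = 0.153 to 0.340). NEO-1 Rep read 1318 for SFN, above every HCaRG-labelled array (1086 to 1299). Without the line block none of the 4 passed (limma adjusted p = 0.987 for each), nor with the tag as a replicate block. CDKN1A, the cell cycle inhibitor p21, read 1920 to 2275 in 3 NEO arrays (1920.2 at least) and 17276 in NEO-1 Rep, against 3749 to 11965 in the HCaRG-labelled arrays. Its log2 fold change was 0.56 ± 0.38 (SE; adjusted p = 0.369), and 1.52 ± 0.34 without NEO-1 Rep (adjusted p = 0.0964). Genes of this list were higher in both arrays tagged Rep than in the other arrays of their line, 17 of 25 in NEO-1 Rep and 20 of 25 in HCaRG-9 Rep. Without NEO-1 Rep the list's adjusted p was 5.21e-07, and 0.143 with an estimated correlation. Without both of these arrays it was 5.02e-07, and 0.00191 with an estimated correlation.

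Mitotic genes passed as a list (39 genes; adjusted p = 0.00305) although none passed alone and 1 rose when adjusted over the list alone; the adjusted p was 0.395 with an estimated correlation. The proliferation marker MKI67 had a log2 fold change of 0.54 ± 0.22 (SE; adjusted p = 0.161), and 0.06 without NEO-1 Rep. NEO-1 Rep held these genes low, with a median log2 difference of -1.21 from the other NEO-1 arrays, and without it the list's adjusted p was 0.629 (0.893 with an estimated correlation). Among 12 epithelial junction and keratin genes EPCAM rose, none fell, and EPCAM alone rose when adjusted over the list alone (list adjusted p = 0.0161; adjusted p = 0.0482 with an estimated correlation). Only 4 of these 12 genes were higher in NEO-1 Rep than in the other NEO-1 arrays, with a median of -0.92, and 3 of 12 in HCaRG-9 Rep than in the other HCaRG-9 arrays, with a median of -0.30. Both medians lay below the range of signal-matched lists. Without NEO-1 Rep the adjusted p was 0.0346 (0.143 with an estimated correlation), and without both arrays tagged Rep 0.000685 (0.000443). For the mitotic list it was 0.228 without both (0.624).

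The other 25 lists had adjusted p-values of 0.0512 to 0.890. Of 30 collagen and matrix genes 3 rose, COL1A1 (379 ± 175 to 818 ± 225), FBN1 and LOX, and none fell (list adjusted p = 0.0512, and 0.0747 with an estimated correlation; 6.56e-05 and 0.0129 without NEO-1 Rep). The 2 tested probe sets of COL1A1 pointed in opposite directions, and without NEO-1 Rep the log2 fold changes of FBN1 and LOX went from 1.05 and 0.74 to 0.43 and 0.39 (adjusted p = 0.302 and 0.393). The Wnt antagonist genes SFRP1 (486 ± 136 to 1019 ± 97.49; log2 fold change 1.11 ± 0.14, SE) and DKK1 (1.17 ± 0.18) and the receptor-degrading ligase gene RNF43 rose among 30 Wnt and Notch genes. Only 10 of these 30 had a log2 fold change above 0 (median -0.05, limma cameraPR adjusted p = 0.746). NRG1, an ErbB receptor ligand, rose from 189 ± 34.5 to 399 ± 14.4 (0.97 ± 0.12), and the endothelin receptor gene EDNRB from 295 ± 89.5 to 541 ± 49.3 (0.90 ± 0.14). The neurofilament genes INA and NEFL, the glucose transporter gene SLC2A3, the sodium pump subunit gene ATP1B1, the apoptosis inhibitor gene MCL1 and THBS1 also rose, with log2 fold changes of 0.53 to 1.05. CD44 and OAS3 rose with 1.01 ± 0.19 and 1.69 ± 0.27, but read 1271 and 167 in HCaRG-8 against 1354 and 267 in NEO-6, and without NEO-1 Rep CD44 had 0.57 (adjusted p = 0.264). MCM7 and RFC2, which encode a replicative helicase subunit and a clamp loader subunit, fell by 0.59 and 0.53 on the log2 scale among 35 replication genes, and ACAT2 and NDUFB10 fell by 0.59 and 0.73. NEO-1 Rep read 21161 for MCM7 and 34492 for NDUFB10, and without it their log2 fold changes were -0.38 and -0.41 (adjusted p = 0.189 and 0.207). Of the genes named in this paragraph so far, COL1A1 and SFRP1 also passed without NEO-1 Rep, and the others had adjusted p-values of 0.0539 to 0.393 there; without the line block none passed (0.436 to 0.987). In HCaRG-8 over NEO-6 the log2 fold changes of FBN1, LOX, DKK1, EDNRB, MCM7 and NDUFB10 were -0.03, 0.03, 0.23, 0.29, -0.17 and -0.22. Those of ACAT2, RFC2, MCL1 and ATP1B1 were -0.22, -0.26, 0.29 and 0.31. Those of COL1A1, SFRP1, RNF43, NRG1, INA, NEFL, SLC2A3 and THBS1 were 0.53 to 1.26. None of the 14 COMMD and partner complex genes passed (median log2 fold change -0.11, mean 0.01, list adjusted p = 0.474). EGFR (-0.10 ± 0.12, adjusted p = 0.636) and VIM (0.09 ± 0.11, adjusted p = 0.629; 0.33 without NEO-1 Rep) did not pass.

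Immediate early genes, which cells induce within minutes of stimulation, did not pass as a list between the labelled groups (20 measured genes, none passed; adjusted p = 0.216; 0.812 with an estimated correlation). All 20 read higher in NEO-1 Rep and HCaRG-9 Rep than in any other array. FOSB read 5517 and 7056 there against 9.1 to 21 elsewhere, and EGR1 43412 and 34360.1 against 1336 to 2428. The median log2 difference from the other arrays of the line was 2.08 in NEO-1 Rep and 1.56 in HCaRG-9 Rep.

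**Figure D3:**
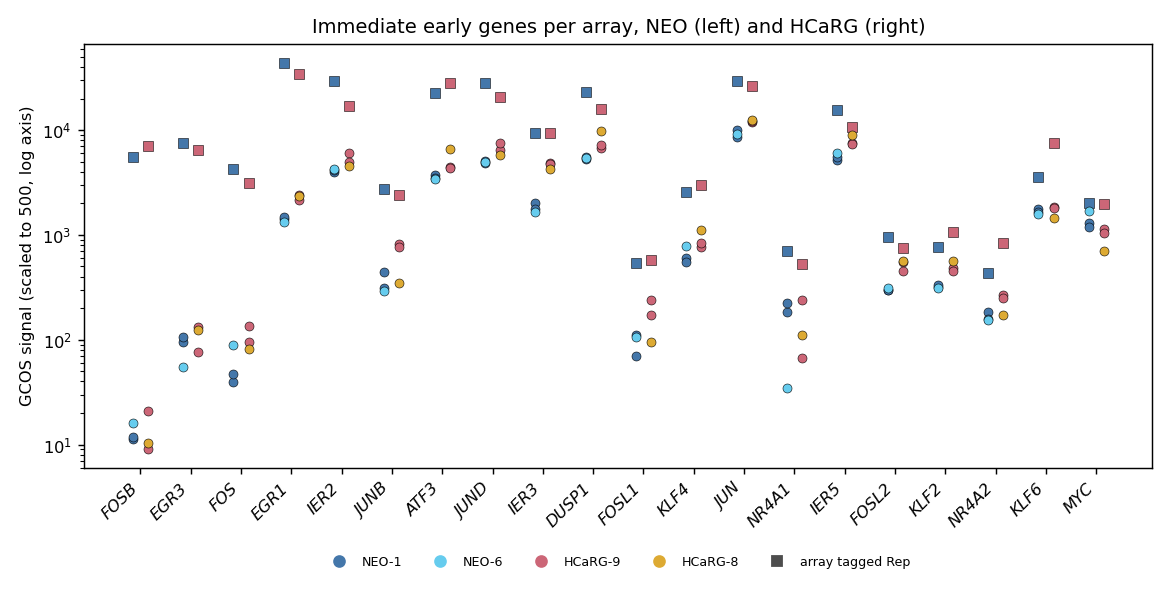
Deposited signal per array on a log axis for 20 immediate early genes, with NEO arrays to the left and HCaRG-labelled arrays to the right of each gene; colours mark the lines and squares the arrays tagged Rep. The squares lie above all other points for each of the 20 genes.

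In all, 503 of 20124 probe sets passed in limma with the line as a random block, 235 higher and 268 lower (328 and 584 after median centring), and 21 genes, 19 higher and 2 lower, passed with and without NEO-1 Rep with the 2 groups of arrays fully apart. The arrays of the 2 groups were fully apart for 457 genes whatever the test, 4.39% of 10418. Chance would give 2.86% if all arrays were exchangeable. Repeat arrays of a line are not independent, so that share is not a chance rate for this design, and no excess is read from it. The count of 503 probe sets depended on a single array and on how the lines were treated. It was 68 without NEO-1 Rep, 40 of them among the 503, 1 without the block, 52 with 1 mean per line, and 0 on the 6 tagged arrays with the tag as a replicate block. It was 1 without NEO-1 first or Rep2, 4766 without NEO-6, 15 without HCaRG-9 first or Rep2, 2 without HCaRG-9 Rep and 902 without HCaRG-8. The balance of directions moved too. Higher and lower calls were 62 and 6 without NEO-1 Rep, 44 and 8 with 1 mean per line, and 63 and 21 with a 2-fold minimum. Lower calls stayed more numerous with another offset, with quantile normalization and without HCaRG-8.

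**Figure D4:**
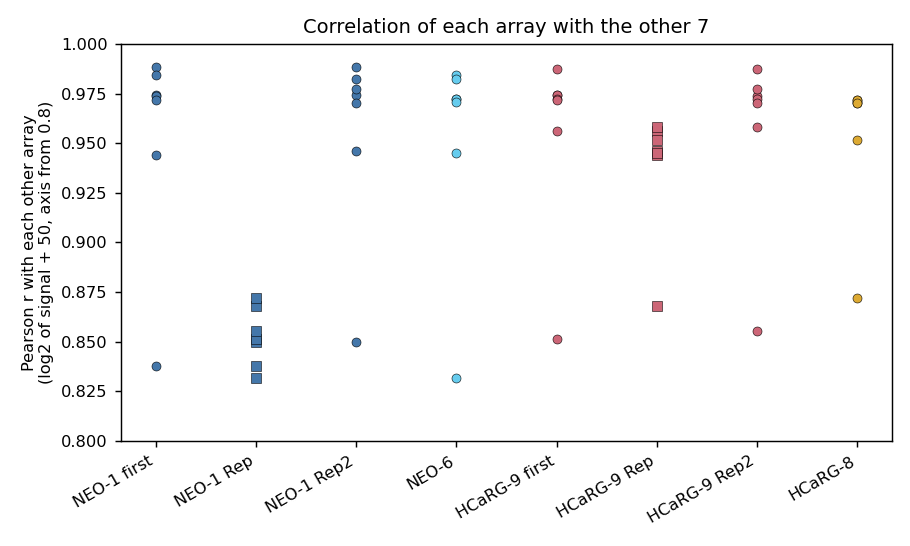
Pearson correlation across tested probe sets, on log2 of signal plus 50, of each array with each of the other 7 (axis from 0.8); colours mark the lines and squares the arrays tagged Rep. NEO-1 Rep correlates at 0.832 to 0.872 with the others, whose correlations among themselves are 0.944 to 0.989.

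The comparison of HCaRG-9 with NEO-1 asked how the lines with repeat arrays differ, and it is a difference between lines as much as between plasmids. LCP1 rose from 66.8 ± 34.4 in NEO-1 to 984 ± 64.0 in HCaRG-9 (SD, n = 3 each; log2 fold change 3.18 ± 0.28, SE; limma adjusted p = 0.0290). PNPLA4, which encodes a patatin-like phospholipase, fell from 470 ± 89.4 (469.8 before rounding) to 18.8 ± 15.8 (-2.93 ± 0.28, adjusted p = 0.0333). In the other pair of lines PNPLA4 read 629.8 in NEO-6 and 1230.2 in HCaRG-8. The third probe set past the threshold is unnamed in the annotation used here and was chosen after its values were seen. It rose from 869 ± 275 to 11870 ± 115 (11869.7 before rounding; log2 fold change 3.74 ± 0.26, adjusted p = 0.0102). In the other pair of lines it read 3242.2 in NEO-6 and 5262.1 in HCaRG-8. These 3 of 20124 probe sets passed, and 772 had an unadjusted p under 0.05. With the tag as a replicate block none passed (adjusted p = 0.108, 0.119 and 0.0573 in the order above); the count was 51 without NEO-1 Rep, 1 without NEO-1 first or Rep2 and 0 without any HCaRG-9 array.

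The 2 lines within each group gave a measure of how far transfectant lines differ without a change of plasmid. SDC3, a heparan sulfate proteoglycan of the cell surface, read 24.6 in NEO-6 and 422.5 to 650 in NEO-1 (650.3 at most; log2 fold change -2.89 ± 0.43, SE; limma adjusted p = 0.951). AMBN, EPDR1 and MAPK13 read higher in NEO-6, with log2 fold changes of 2.01 ± 0.46, 1.84 ± 0.37 and 1.55 ± 0.34, and OLFML2A lower, with -1.67 ± 0.33 (SE). Between the HCaRG lines, PNPLA4 differed by 4.24 ± 0.38 (adjusted p = 0.0768), and EPDR1 by 2.39 ± 0.37, both with the higher value in HCaRG-8. The meiotic cohesin gene REC8 read 36.4 in HCaRG-8 and 617 to 905 in HCaRG-9 (-3.21 ± 0.40), and MAP7D2 and the interferon-inducible DNA sensor gene IFI16 read 2.5 and 2.4 in HCaRG-8 against 421.5 to 427 and 223 to 336.5 in HCaRG-9. None of these passed: limma found 0 probe sets between the NEO lines and 0 between the HCaRG lines, with 126 and 250 at an unadjusted p under 0.05 where 1006 are given by chance. NEO-6 and HCaRG-8 had 1 array each, assumed to vary like the repeat arrays; without NEO-1 Rep, which widens that spread, 8 probe sets passed between the HCaRG lines.

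The pair HCaRG-8 and NEO-6 asked whether the difference seen between the lines with repeat arrays is also seen in a second pair. LCP1 read 749.5 in HCaRG-8 and 76.6 in NEO-6 (log2 fold change 2.66 ± 0.48, SE), and SDC3 498.6 and 24.6 (2.88 ± 0.52). MAP7D2 (-3.57 ± 0.57), IFI16 (-2.90 ± 0.49) and REC8 (-2.50 ± 0.50) were lower in HCaRG-8 by value. The difference between the line pairs, HCaRG-9 over NEO-1 minus HCaRG-8 over NEO-6, was largest by moderated t for MAP7D2 (3.85 ± 0.66), PNPLA4 (-3.84 ± 0.54), the transketolase-like gene TKTL1 (-3.71 ± 0.67), REC8 (3.36 ± 0.57) and IFI16 (3.30 ± 0.57), and these contrasts share the HCaRG-8 array. None of these values passed: limma found 0 probe sets for the second pair and 0 for the difference between pairs, with 115 and 172 at an unadjusted p under 0.05 and smallest adjusted p-values of 0.99996 and 0.999. Without NEO-1 Rep 1 probe set passed for the second pair.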

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

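The tests of the 3'/5' ratio, of the rises in both arrays tagged Rep and of the correlation between arrays of a line were chosen after those results were seen; the others were written down first. In groups of 4 arrays, 25 of 156 group values had an array far from the other 3 by a gap test (Dixon) that by chance marks about 1 in 20; chance gives 7.8, and 16 of the 25 were for NEO-1 Rep, so they are not independent of each other.

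NEO-1 Rep lay far above the other NEO arrays for the 2 COMMD5 probe sets shared with other genes (3841 against 1725 to 1846, and 3334 against 1655 to 1859) and for the brighter one that names only COMMD5 (1805 against 761 to 929.7). It was also far above them for CDKN1A (17276), VIM (55826), BEX1 (573), CD24 (1123), ZNF853 (2175), SHROOM1 (3637), ABCA3 (1348), PRKCQ-AS1 (1082.5) and KHDC1 (2056), and far below them for CD44 (648 against 1282 to 1395). Its 75th percentile of signal was 376 against 478 to 482, its median correlation with the other arrays 0.851 against 0.972 to 0.974, and the hybridization control bioC 5038 against 3049 to 3290.4. HCaRG-9 Rep was far above the other HCaRG-labelled arrays for TCIM (3563), H2AC6 (1298), TP53INP1 (3202) and ID2 (8927), and its median correlation was 0.946 against 0.970 to 0.972. HCaRG-8 was far from the HCaRG-9 arrays for PNPLA4 (1230.2 against 6.4 to 36.6), CD44 (1271 against 2288 to 2490.3), EGFR (805 against 548 to 586) and NDUFB10 (17032 against 12021 to 12642).

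The first pattern weighed is that NEO-1 Rep stands apart from the other 7 arrays. RNA degraded from the 5' end is argued against by its mean log2 3'/5' ratio of GAPDH and ACTB, 0.195 where the other arrays had 0.13 to 0.28. A different shape of the signal distribution is argued against by its median correlation after quantile normalization, 0.843 where the lowest pair among the others had 0.945. Of the other-cell markers, 0 were above 1000 in NEO-1 Rep and over 3 times the highest other array, with COL1A1 the brightest at 637. A small share of cells, or a cell type without these markers, would give 0 too, so this does not decide on cells of another type. Labelling that depends on gene length stays open as a candidate explanation: across 10414 genes, which are not independent, its deviation from the other arrays correlated with gene length at a Spearman rho of -0.452, and the largest absolute value elsewhere was 0.223. A change of transcription in the culture that favours short genes would give that trend too, and the design offers no group with which to test a biological explanation. The rho was 0.220, 0.223 and 0.193 in NEO-1 first, NEO-1 Rep2 and NEO-6. It was 0.024, 0.076, -0.078 and -0.161 in HCaRG-9 first, Rep2, Rep and HCaRG-8. The labels thus differ in this trend without NEO-1 Rep too, and no fit was adjusted for gene length.

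The second pattern is that 20 of 20 immediate early genes and 14 of 18 genes of the integrated stress response were higher in both arrays tagged Rep than in the other arrays of their lines. In HCaRG-9 Rep the median log2 rise was 1.56 for 20 immediate early genes and 0.61 for 18 stress genes, where the central 95% of 10000 signal-matched lists ended at 0.21 and 0.20. In NEO-1 Rep the medians were 2.08 and 0.77 where that range ended at 0.59 and 0.62. A rise in HCaRG-9 Rep is part of how this pattern was defined. For the immediate early genes, although their list was fixed beforehand, that rise therefore does not test a disturbance of the NEO-1 Rep array alone. Genes such as FOSB, FOS and EGR3 also passed the filter on mean signal only through the arrays tagged Rep. The stress genes were picked after the pattern was seen, and for both sets the values restate it, so they do not decide for a difference between the runs; no cause in the cultures or the RNA was tested.

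The third pattern is the count of 503 probe sets between the HCaRG-labelled and NEO arrays. The estimated correlation between arrays of a line, -0.317 with 8 arrays, was 0.06 without NEO-1 Rep (0.0569 unrounded) and at most -0.225 without any other array, so a single array that stands apart may set the negative correlation. The count did not follow the correlation alone. It was 2 at -0.315 without HCaRG-9 Rep and 902 at -0.326 without HCaRG-8. Chance cannot be excluded: 3 of the 35 splits of the 8 arrays gave as many probe sets, and the highest other gave 8819. That split set NEO-1 first, NEO-1 Rep2, NEO-6 and HCaRG-8 against NEO-1 Rep and HCaRG-9, and its count was several times the real one. It divides NEO-1 between the groups, so the line block enters its fit differently. Whether its count reflects the samples or the fit was not tested. The other split that keeps the lines whole, NEO-1 with HCaRG-8 against HCaRG-9 with NEO-6, gave 1559. Without NEO-1 Rep chance cannot be excluded either, since 2 of 35 splits gave as many as the real 68, but the higher one set HCaRG-9 against all others (98), and NEO-1 with HCaRG-8 against HCaRG-9 with NEO-6 gave 0.

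For HCaRG-9 against NEO-1, 1 of 10 splits, the real one, gave as many as 3 probe sets and the highest other gave 0; 10 splits are too few for a share under 0.05.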

How the results depend on the processing

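Fits without NEO-1 Rep other than the plain leave-out, without both arrays tagged Rep, with array weights, and list tests with the replicate block were chosen after seeing the data. The number of arrays limits all counts, and dim probe sets are limited by signal over background. For HCaRG against NEO (503 probe sets) the count was 84 with a 2-fold minimum, 44 with no filter, 912 with median centring, 1 with no block on the line, 52 with line means, 3 with the HCaRG-9 and NEO-1 arrays alone, 0 with line coefficients, 0 with the replicate block on the tags, and 1 to 4766 with an array left out. Without NEO-1 Rep it was 86 with no block and 14 with line means, without both arrays tagged Rep 65, and 2143 with array weights and no block. It was 356 to 722 in the other settings. Without NEO-1 Rep the correlation between arrays of a line was no longer negative (0.0569). The cause was not tested for that move or for the others.

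For HCaRG-9 against NEO-1 (3) it was 1 with no offset, with no filter and with a mean signal of at least 500, 0 with the replicate block, 0 to 51 with an array left out, and 1855 without both Rep arrays. Between the HCaRG lines (0) it was 2 with no offset, 1 with 1 probe set per gene and 0 to 8 with an array left out. For HCaRG-8 against NEO-6 (0) an array left out gave 0 to 1. The NEO lines and the difference between pairs gave 0 throughout. COMMD5 stayed short of the threshold in every setting, with log2 fold changes of -0.15 to 0.21.

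For gene lists (4 past the threshold) the count was 2 with an estimated correlation, 7 with HCaRG-9 against NEO-1 (8 with the replicate block), 13 with line means, 11 with no filter and 3 to 12 with an array left out. Without NEO-1 Rep it was 12 with no block and 2 with an estimated correlation. Without both Rep arrays it was 12, and 10 with an estimated correlation. TGF-beta and BMP signalling passed in all of these.

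Of 63 named results for HCaRG against NEO, none turned direction past the threshold. With no block on the line 58 fell short, with line means 42, with no filter 45, with line coefficients 59, with the replicate block 59, and over the 8 left-out arrays 318 of 504. At most 7 fell short with another offset, normalization or trend. The tags were taken to pair the arrays; beyond the calls given here the replicate block changed no other call.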

Other observations

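The test of rises in both arrays tagged Rep was chosen after those arrays had been seen to differ. All 20 measured immediate early genes, transcription factors and feedback regulators that cells induce within minutes of stimulation, read higher in NEO-1 Rep and in HCaRG-9 Rep than in any of the other 6 arrays. FOSB read 5517 and 7056 in these arrays against 9.1 to 21 in the others, EGR3 7584.5 and 6441 against 55.1 to 131, and FOS 4292 and 3160.0 against 39.9 to 134. EGR1 read 43412 and 34360.1 against 1336 to 2428, and ATF3 22658 and 28037 against 3398 to 6586, while MYC showed the smallest rise in NEO-1 Rep, 2027 and 1966 against 707 to 1694. The labels give the same synchronization, 10% serum and 48 hours for every array.

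Of 18 genes of the integrated stress response, a part of a fixed list picked after the arrays were seen, 15 read higher in NEO-1 Rep and 16 in HCaRG-9 Rep than in the other arrays of the line, 14 of them in both; VLDLR read lower in both, SLC7A11 and PSAT1 in NEO-1 Rep and PHGDH in HCaRG-9 Rep. TRIB3, a pseudokinase induced by amino acid shortage, read 10371 in NEO-1 Rep and 3647 in HCaRG-9 Rep against 1166 to 1381 elsewhere, CHAC1 2757.5 and 780.5 against 226 to 363, and SESN2 9801 and 4065 against 1329.9 to 1749. Of 29 lists, 5 had a median rise above the range holding the central 95% of signal-matched lists in both arrays: immediate early genes, NF-kB targets and cytokines, CDK inhibitors and p53 targets, the unfolded protein and stress response, and Wnt and Notch targets. Within the list that joins the unfolded protein and stress responses, the 18 integrated stress genes had medians of 0.77 in NEO-1 Rep and 0.61 in HCaRG-9 Rep, and the other 17 had 0.06 and 0.19, the latter just under its matched limit of 0.21; the difference between the parts was not tested. Mitotic genes lay below the matched range in both arrays, with medians of -1.21 in NEO-1 Rep and -0.33 in HCaRG-9 Rep, and so did epithelial junction and keratin genes, with -0.92 and -0.30. Heat shock protein genes had medians of -1.63 and -0.20, below the matched range of -0.61 to 0.73 in the first and within -0.20 to 0.25 in the second.

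With both arrays tagged Rep left out, the immediate early list was shifted higher in the HCaRG-labelled arrays (limma cameraPR adjusted p = 1.35e-09; adjusted p = 4.71e-11 with an estimated correlation), with 9 of 20 genes higher and 1 lower when adjusted over the list alone. With 8 arrays its adjusted p was 0.216, and 2.52e-07 without NEO-1 Rep, but 0.812 and 0.307 with an estimated correlation. The estimate was 0.897 with 8 arrays. Without both arrays tagged Rep the adjusted p with an estimate was smaller than at 0.01, so there it is no stricter check. The median log2 deviation from the mean of the 8 arrays lay at -0.68, -0.66 and -0.67 in the NEO arrays, at -0.20 and -0.26 in HCaRG-9 first and Rep2 and at -0.54 in HCaRG-8. In HCaRG-8, 8 of the 20 genes read no higher than in the highest of these NEO arrays: FOSB, FOS, JUNB, FOSL1, NR4A1, NR4A2, KLF6 and MYC. IER3 read 4254 to 4857 in these HCaRG-labelled arrays and 1660.1 to 2012 in the NEO arrays. In all, 12 of 29 lists passed on these 6 arrays, all toward higher values in the HCaRG-labelled arrays (10 with an estimated correlation). Collagen and matrix genes were among them (adjusted p = 2.42e-06, and 1.00e-07 with an estimated correlation), with 2 of 30 genes up. Cytosolic ribosomal protein genes had the smallest limma cameraPR adjusted p of the lists, 5.82e-11, but 0.219 with an estimated correlation. These rest on 2 lines per label, and chance cannot be excluded for the calls of that comparison without NEO-1 Rep.

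Of the 21 genes that passed with and without NEO-1 Rep with the groups fully apart, 8 lie outside the rule for named genes and are given here after their values were seen. HLA-DPA1 and HLA-DQB1, which encode chains of MHC class II molecules, rose with log2 fold changes of 0.88 ± 0.12 and 0.79 ± 0.14 (SE; limma adjusted p = 0.0124 and 0.0256). The cysteine protease genes CTSF and CTSH rose with 1.10 ± 0.25 and 0.73 ± 0.12, and TFPI2, a secreted protease inhibitor, with 0.71 ± 0.10. EMILIN2 rose with 1.21 ± 0.17, PPP2R2C with 1.15 ± 0.15 and DMKN with 1.07 ± 0.16. None of these 8 genes passed without the line block, where LCP1 alone did, or with the tag as a replicate block.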
